A study of Orbilia oligospora with 12 samples.

How the data were processed

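RNA from hyphae of Arthrobotrys oligospora was sequenced on Illumina libraries, per the labels' protocols, for 4 groups of 3 libraries: the wild type and a strain labelled ΔAorlmA, each at 0 h and 48 h with nematode extract. Groups were taken from the genotype and time labels and replicate numbers from the titles. The labels call the replicates biological and say no more of separate cultures. The growth protocol of the labels names a different deletion strain (ΔAosnf1), so the gene annotated as SNF1 was looked up as well and was not lost: AOL_s00173g192 had 106 ± 3.17 TPM in the wild type at 0 h and 43.1 ± 9.42 TPM in the libraries labelled ΔAorlmA at 0 h (mean ± SD, n = 3).

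The authors deposited expression values as TPM, rounded to 2 decimals; the values of each library add up to the scale of the unit. A second deposited table gives FPKM values with annotations (Swiss-Prot, KEGG orthology, Pfam); within a library FPKM was the TPM value times a constant, to within 0.41%. The authors also deposited sequencing statistics, with the percent of bases of quality 30 (94.3% to 94.7%) and the GC percent (47.9% to 48.4%) of the clean reads. A table of the authors' own calls, without fold changes or p-values, was used only for comparison. The table named for raw counts held correlations between libraries, which match Pearson correlations of TPM to within 5e-05, so no counts per gene were used here. The aligner, the quantifier, the genome build and the trimming tool are not given in the sources used here. A total of 8 columns of group means were left out, since they hold no replicates, as were 2 tables of read statistics that repeat the first.

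All gene names matched locus tags of the RefSeq table given with the data, and 7737 carried an annotation. Lengths were multiples of 3 for 99.98% of the genes, so they are coding lengths. The depth was 48.9 to 61.6 M raw reads and 48.5 to 61.1 M clean reads per library (99.0% to 99.3% of the raw). Low FPKM values of genes of 500 to 1000 bases fell on steps that correspond to whole fragments (100% of 248 to 295 values per library within 0.15 of a whole number), which gave an estimate of 12.5 to 15.7 M assigned fragments per library. The share of the error that comes from depth was not separated from the spread between libraries. Genes listed at 0 in a library (1015 to 1505 genes) are not called absent.

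Because no counts per gene were used, the test differs from the count test first planned, and the planned fallback for normalised values was used. Genes with at least 1 TPM in at least 3 libraries were tested (9355). A single limma fit (version 3.58.1, R 4.3.3; lmFit, eBayes with a variance trend, not robust) on log2(TPM + 1) used all 12 libraries with a mean per group and no replicate block. Fold changes are on that scale and understate the change of low genes. The contrasts were the strains at 0 h and at 48 h, 48 h against 0 h in either strain, and the interaction. Tests were two-sided with Benjamini-Hochberg adjustment over all genes tested, a call being an adjusted p under 0.05; the number that also changed at least 2-fold (1 on the log2 scale) is given beside it. The gene targeted in the labels was also tested with an exact permutation test.

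From annotation terms, 33 gene lists were fixed before the data were examined, as were the groups, the tests, most of the other settings tried and the rule for named genes. Keyword matching lets in genes that do something else, and such members are named where they come up. The 31 lists with at least 5 tested members were tested with camera (limma, preset correlation 0.01, Benjamini-Hochberg over the lists of a contrast); every list call of the report was lost with a correlation estimated from the data. The lists of MADS-box genes (3 tested) and of spore and hydrophobin genes (4 tested) were read gene by gene.

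Genes were named by a rule. For each pairwise comparison it takes the MADS-box genes, the 5 largest rises and the 5 largest falls among annotated genes that were called, had at least 5 TPM in the higher group and had all 3 libraries of a group above all 3 of the other, and from each list the called member with the lowest adjusted p and, in lists with at least 5 called members, the lowest in the other direction, up to 30 genes. For the interaction it takes the 10 genes with the lowest adjusted p. Genes without annotation that outranked the annotated ones numbered 4 higher and 6 lower at 0 h, 8 and 3 at 48 h, 7 and 2 over time in the wild type and 4 and 6 over time in the strain labelled ΔAorlmA.

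The fit was tested on simulated data, with 200 of 9355 genes changed by known folds. Libraries were drawn with each gene's mean over all 12 libraries and its residual SD, with independent normal noise. A further set of genes, shifted less for the list test, was left out of the false calls. Of genes changed 4-fold it recovered 74% at 0 h, 73% at 48 h, 65% over time in the wild type, 68% over time in the strain labelled ΔAorlmA and 33% for the interaction; of genes changed 2-fold it recovered 15%, 12%, 6%, 11% and 2%. False calls made up 7.29%, 8.60%, 4.00%, 4.82% and 2.78% of the calls. These rates need not hold for the real data, where far more genes were called and single libraries stood apart from their groups.

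The alternatives were FPKM in place of TPM, a pseudocount of 0.1, no filter, a mean of at least 5 TPM, median-of-ratios scaling, quantile normalization, only the groups compared, no variance trend, the replicate number as a block, each library left out in turn, and for lists an estimated correlation and fry. Precision weights (voom) from the estimated fragments, the lists under quantile normalization and the fit without the first libraries labelled ΔAorlmA were added after seeing the data. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 served for tables, permutation tests and plots.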

Results

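RNA-seq libraries of Arthrobotrys oligospora, a soil fungus that catches nematodes in sticky networks of hyphae, were compared between the wild type and a strain labelled as lacking AorlmA. AorlmA codes for a MADS-box transcription factor of the Rlm1 type, known in yeast as a target of the cell wall integrity MAP kinase pathway. Hyphae grown on potato dextrose agar at 28 °C for 5 days were sampled at 0 h and 48 h of induction with a nematode extract, which triggers the formation of traps. Each of the 4 groups (wild type at 0 h and 48 h, labelled ΔAorlmA at 0 h and 48 h) held 3 libraries, 12 in all, which the labels call biological replicates without saying how they were grown apart. The p-values therefore measure only the spread between these samples, which may in part be technical. The libraries held 48.5 to 61.1 M clean reads (median 56.4 M), and 8450 to 9177 genes reached 1 TPM in each. Of all genes, 9355 were tested.

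The first principal component held 40.7% of the variance of the log2 values and the second 32.5%. The wild-type libraries resembled each other closely, with mean Pearson correlations within their group (across genes, which are not independent replicates) of 0.949 to 0.963 at 0 h and 0.973 to 0.979 at 48 h. The third at 0 h lay further out on the second component, which separated the strains (73.7, against 40.5 and 39.5 for its group). Its mean correlation with the 0 h libraries labelled ΔAorlmA was 0.799, against 0.874 and 0.873 for the first and second. A pair of the libraries labelled ΔAorlmA stood apart. The first at 0 h had a mean correlation of 0.903 with its own group and reached 0.924 with a 48 h library of the same strain label. The first at 48 h had a mean correlation of 0.932 with its own group and reached 0.944 with a wild-type library of 48 h. The total of genes called in each comparison is also given without both, an alternative chosen after seeing the data. It is called here the fit without the first ΔAorlmA libraries. Leaving out libraries that stood apart narrows the spread within their groups, and the first at 48 h lay nearest the wild type. Larger counts under this fit are therefore favoured by the choice and give no support to a result.

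**Figure D1:**
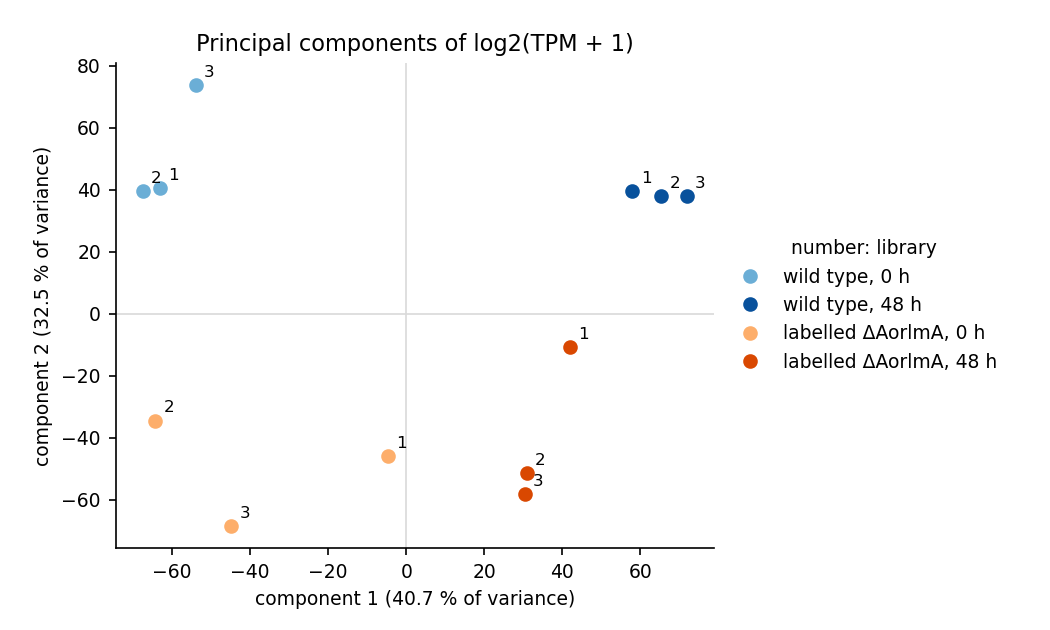
Scores of the 12 libraries on the first and second principal components of log2(TPM + 1), which hold 40.7% and 32.5% of the variance; each point is a library, coloured by its group. The first library labelled ΔAorlmA at each time lies away from the others of its group. On the second component so does the third wild-type library at 0 h.

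The targeted gene was examined first. The labels give no locus for AorlmA beyond titles that begin with A125, the number that ends AOL_s00078g125, and 3 genes carry a MADS box in the annotation. AOL_s00078g125, annotated as SMP1 and RLM1 and the closest match to the name, was not lost in the libraries labelled ΔAorlmA. At 0 h it had 36.2 ± 5.24 TPM in the wild type and 117 ± 45.8 TPM in the libraries labelled ΔAorlmA (mean ± SD, n = 3), a ratio of 3.24 (log2 fold change 1.60, SE 0.31, limma adjusted p = 0.00298). At 48 h it had 35.1 ± 8.92 and 97.6 ± 10.7 TPM, a ratio of 2.78 (log2 fold change 1.47, SE 0.31, adjusted p = 0.0092). Every library labelled ΔAorlmA lay above every wild-type library, and the two-sided exact permutation test gave p = 0.1 at both times, the smallest that 3 libraries against 3 allow. AOL_s00112g128, annotated as MCM1, which in yeast regulates mating and cell cycle genes, had 188 ± 11.4 and 188 ± 10.9 TPM at 0 h and 346 ± 32.6 and 240.9 ± 43.6 TPM at 48 h, and passed in neither (adjusted p = 0.991 and 0.0791), though at 48 h it was called lower under quantile normalization (-0.64, adjusted p = 0.0422). AOL_s00088g15, a short gene with an SRF-type domain, was lower at 0 h (32.6 ± 6.6 against 15.3 ± 5.58 TPM, log2 fold change -1.07, adjusted p = 0.0189), a call that ended under median-of-ratios scaling (-0.54, adjusted p = 0.216) and without the third wild-type library (adjusted p = 0.0732). No gene had at least 1 TPM in all 6 wild-type libraries and 0 in all 6 libraries labelled ΔAorlmA (0 genes). Because the targeted gene goes against the label, the strain is called by its label throughout, and every direction between strains is a direction between libraries so labelled.

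**Figure D2:**
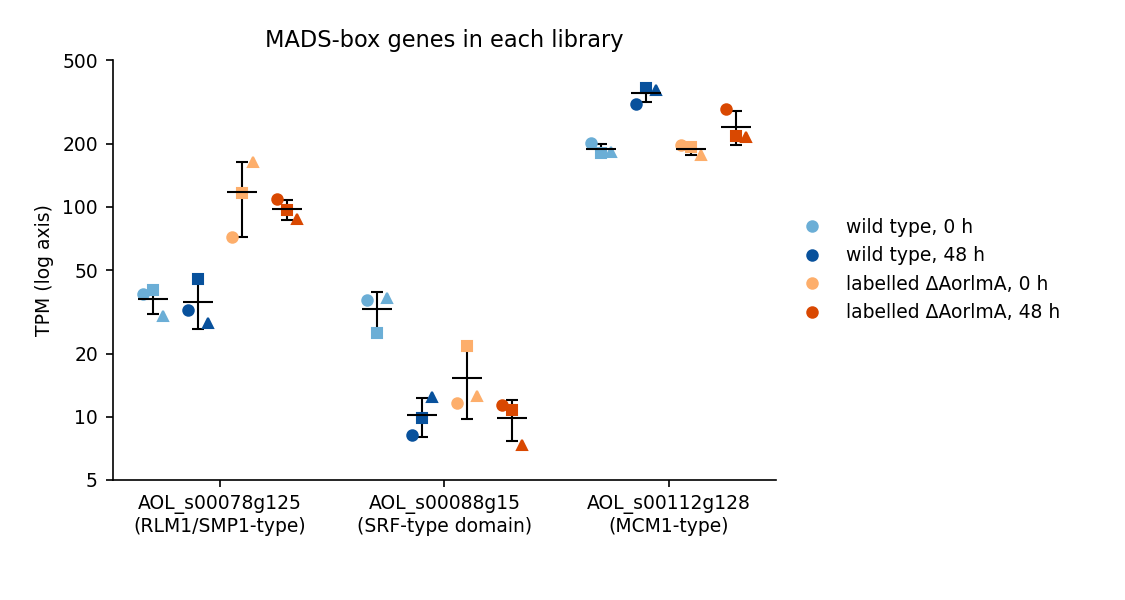
TPM of the 3 genes annotated with a MADS box in each library (points), with the mean and SD of each group of 3. AOL_s00078g125, the RLM1-type gene, is higher in the libraries labelled ΔAorlmA at both times (36.2 against 117 TPM at 0 h, 35.1 against 97.6 TPM at 48 h).

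The comparison at 0 h asked which genes differ between the strains before traps are induced. Among annotated genes the largest rises included the cluster around the 6-methylsalicylic acid synthase gene, AOL_s00215g274 to AOL_s00215g283, known as the source of the arthrosporols, hybrids of a polyketide and a terpene. Of its 10 genes 9 were higher in the libraries labelled ΔAorlmA (9 adjusted over the list alone), with a median log2 fold change of 5.28 and camera adjusted p = 2.98e-13, or adjusted p = 0.795 with an estimated correlation. The cytochrome P450 gene AOL_s00215g278 had 3.10 ± 0.886 TPM in the wild type and 447 ± 353 TPM in the libraries labelled ΔAorlmA (n = 3 each, log2 fold change 6.52, SE 0.74, adjusted p = 0.000298). The prenyltransferase AOL_s00215g276 went from 5.40 ± 2.27 to 578 ± 451 TPM, the cupin oxidoreductase AOL_s00215g277 from 18.6 ± 8.80 to 1154 ± 701 TPM and the synthase AOL_s00215g283 from 0.833 ± 0.566 to 129 ± 122 TPM. AOL_s00215g274, a dehydrogenase at the edge of the cluster, did not pass, with 194 ± 31.4 and 722 ± 541 TPM. Outside the cluster, the serine protease inhibitor AOL_s00006g563 (6.10 ± 5.47 and 432 ± 286 TPM) and the oxidoreductase AOL_s00043g281 (12.6 ± 11.5 and 967 ± 1312 TPM) were among the 5 annotated genes with the largest rise.

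**Figure D3:**
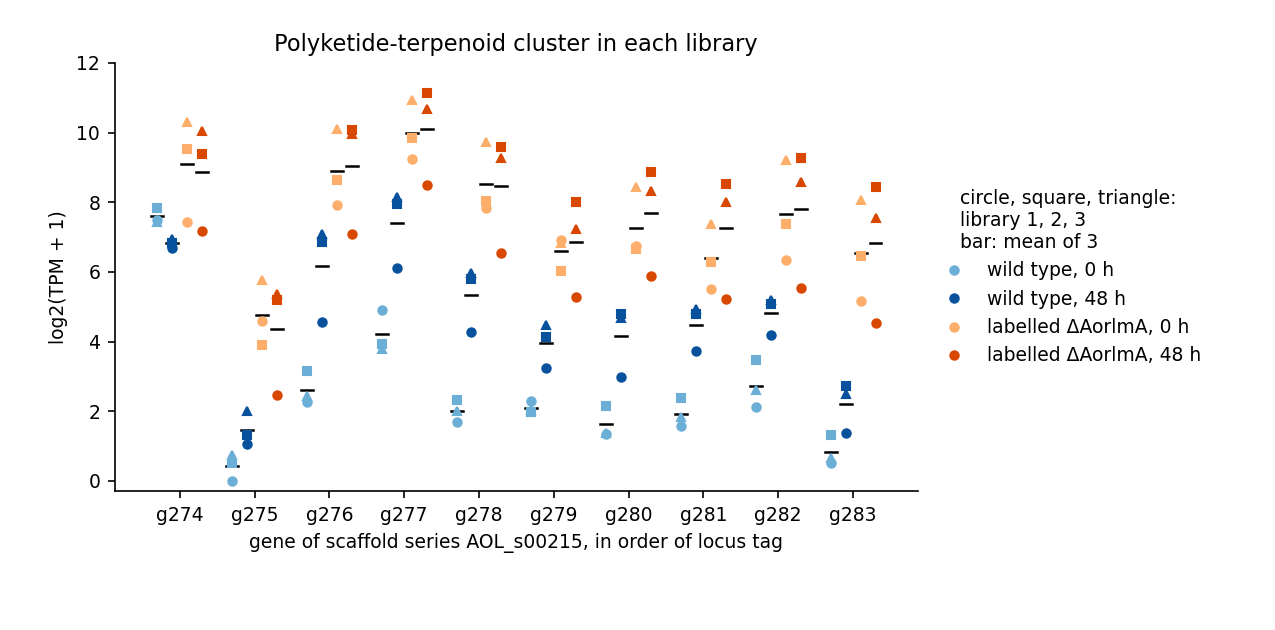
TPM on a log axis of the genes AOL_s00215g274 to AOL_s00215g283 in each library, coloured by group. For AOL_s00215g278 the wild-type mean is 3.10 TPM at 0 h and 44.9 TPM at 48 h, against 447 and 496 TPM in the libraries labelled ΔAorlmA.

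The largest falls among annotated genes at 0 h included carriers of sugars and organic acids. The sugar transporter MST7 gene AOL_s00080g195 had 1406 ± 210 TPM in the wild type and 113 ± 150.02 TPM in the libraries labelled ΔAorlmA (log2 fold change -5.04, SE 1.03, adjusted p = 0.004). The glucose transporter AOL_s00054g267 fell from 41.6 ± 8.35 to 1.49 ± 1.11 TPM (-4.17, SE 0.32, adjusted p = 4.43e-05) and the mitochondrial 2-oxoglutarate/malate carrier AOL_s00215g29 from 80.8 ± 11.7 to 6.42 ± 5.57 TPM. AOL_s00188g307, annotated as a FAD-dependent oxidase, went from 644 ± 255 to 20.05 ± 19.0 TPM. Over the whole list of transporters 29 of 198 members were higher and 63 lower (31 and 63 adjusted over the list alone), 41 and 26 under median-of-ratios scaling, and the list as a set did not pass (adjusted p = 0.285). Of the 27 nitrogen genes 2 were higher and 17 lower (2 and 17 adjusted over the list alone; 3 and 6 under median-of-ratios scaling; median -1.04, adjusted p = 0.134).

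Genes of the cell wall went both ways at 0 h. FKS1 (AOL_s00054g491), the catalytic subunit that spins the beta-glucan of the wall, had 71.5 ± 5.31 TPM in the wild type and 397 ± 114 TPM in the libraries labelled ΔAorlmA (log2 fold change 2.42, SE 0.25, adjusted p = 0.000193). The chitin synthase regulatory factor AOL_s00112g114 had 45.8 ± 6.56 and 120.4 ± 12.9 TPM (1.38, adjusted p = 0.00195). The glucosidase AOL_s00006g283, which trims glucan, was lower (-1.30, adjusted p = 0.00367), as was the endochitinase AOL_s00215g801 (-1.23, adjusted p = 0.00631), a call that ended under quantile normalization. The chitin list had 8 of 23 members higher and 4 lower (9 and 5 adjusted over the list alone). Its median was -0.00, its mean 0.27 and its test upward (adjusted p = 0.00787; adjusted p = 0.889 with an estimated correlation), and under median-of-ratios scaling the median was 0.54. The glucan list had 6 of 32 higher and 7 lower (7 and 7 adjusted over the list alone), and the list of mannan and GPI-anchored proteins 7 of 73 and 24 (7 and 24), which turned to 11 and 3, and 14 and 7, under median-of-ratios scaling. Neither passed as a set (adjusted p = 0.131 and 0.782). Of the MAP kinase list 6 of 76 were higher and 15 lower (6 and 13 adjusted over the list alone), 14 and 3 under median-of-ratios scaling. PBS2 (AOL_s00097g443), the kinase of the osmotic stress pathway, was higher in the libraries labelled ΔAorlmA (17.1 ± 4.57 against 141 ± 34.6 TPM, log2 fold change 2.98, adjusted p = 0.000583). It was counted in the autophagy list, where 4 of 112 members were higher and 43 lower (4 and 39 adjusted over the list alone; 9 and 12 under median-of-ratios scaling).

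Members of the surface, spore and secreted lists were more often lower than higher at 0 h, a balance that median-of-ratios scaling turned in 3 of 4 lists. The same held for all 9355 genes tested, of which 830 were higher and 3160 lower. The hydrophobin AOL_s00006g570, a rodlet protein that coats conidia and aerial hyphae, had 2449 ± 578 TPM in the wild type and 222 ± 183 TPM in the libraries labelled ΔAorlmA (log2 fold change -3.96, SE 0.99, adjusted p = 0.00868). A second hydrophobin, AOL_s00007g172, was lower (-2.03, adjusted p = 0.00229), as was AOL_s00006g324, named for sporulation-specific protein 5 (-2.47, adjusted p = 0.00139). The conidiation list had 6 of 29 members higher and 10 lower (6 and 10 adjusted over the list alone; 9 and 5 under median-of-ratios scaling), and its called members include thiamine pyrophosphokinase AOL_s00210g121 (2.27, adjusted p = 0.00272), an enzyme of vitamin metabolism. In the list of trap adhesion proteins, kept for lectins and sticky surface proteins, 11 of 103 were higher and 28 lower (10 and 26 adjusted over the list alone; 20 and 10 under median-of-ratios scaling). The ricin-type lectin AOL_s00193g183 fell from 16.7 ± 6.52 to 0.29 ± 0.502 TPM (-3.78, adjusted p = 0.000516). Subtilisins digest the cuticle of caught nematodes. In that list 6 of 46 were higher and 14 lower (6 and 15 adjusted over the list alone; 9 and 6 under median-of-ratios scaling). The subtilase AOL_s00054g992 went from 147 ± 32.4 to 19.7 ± 9.90 TPM (-2.91, adjusted p = 0.00146), while AOL_s00006g563 in the same list is an inhibitor and not a protease. Of the secreted peptidases 6 of 69 were higher and 30 lower (6 and 31 adjusted over the list alone; 9 and 12 under median-of-ratios scaling). Carboxypeptidase S (AOL_s00140g64) was lower (-1.93, adjusted p = 0.000943), and the chaperone BCS1 (AOL_s00007g336), which folds a mitochondrial protein, was higher (1.59, adjusted p = 0.00261). None of these lists passed as a set (camera adjusted p = 0.45, 0.211, 0.514 and 0.475). Set against the other genes, the direction was up for conidiation, trap adhesion and subtilisins, and down for secreted peptidases.

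The lists of the proteasome, DNA repair, the cell cycle and DNA replication were lower at 0 h in the libraries labelled ΔAorlmA under the TPM scale, and ribosome biogenesis was higher. Of 36 proteasome genes none was higher and 29 were lower (31 adjusted over the list alone, median -0.86, adjusted p = 0.00106). DNA repair had 1 of 76 higher and 43 lower (1 and 49 adjusted over the list alone, median -0.95, adjusted p = 0.00403). The cell cycle had 1 of 82 and 35 (1 and 36, median -0.91, adjusted p = 0.0155) and DNA replication 0 of 40 and 21 (0 and 22, median -0.92, adjusted p = 0.0257). Ribosome biogenesis had 18 of 67 higher and 10 lower (17 and 9 adjusted over the list alone, median 0.33, adjusted p = 2.62e-05). Each of these 5 had adjusted p = 0.889 with an estimated correlation. The same value held for oxidative phosphorylation (3 of 74 higher and 32 lower, 3 and 33 adjusted over the list alone, median -0.61, adjusted p = 0.0311) and protein processing in the ER (3 of 83 and 45, 3 and 48, median -0.81, adjusted p = 0.0399), calls that ended under median-of-ratios scaling (adjusted p = 0.938 and 0.275). Under that scaling the single-gene counts shrank to 0 higher and 0 lower for the proteasome, 2 and 9 for DNA repair, 3 and 7 for the cell cycle and 3 and 3 for DNA replication, and ribosome biogenesis had 32 higher and 3 lower. Without the first ΔAorlmA libraries 29 proteasome, 56 DNA repair, 67 cell cycle and 30 DNA replication genes were lower. Ribosome biogenesis then had 23 higher and 15 lower. The lists that did not pass are given with the counts adjusted over the list alone in parentheses. They held 5 of 54 peroxisome genes higher and 8 lower (5 and 7), 1 of 112 and 7 for the ribosome (0 and 0) and 6 of 85 and 32 for endocytosis (7 and 32). Fatty acid breakdown had 5 of 18 and 2, a balance that its own adjustment turned (6 and 7). Further lists held 4 of 53 and 15 for the TCA and glyoxylate cycles (4 and 15), 5 of 38 and 11 for glycolysis (5 and 11), 5 of 74 and 19 for oxidative stress (5 and 16) and 4 of 110 and 34 for heat shock (4 and 32). The last held 5 of 62 and 21 for G protein signalling (5 and 21), 12 of 220 and 81 for the cytoskeleton (12 and 83), 11 of 49 and 22 for secondary metabolism (11 and 23) and 7 of 94 and 32 for plant wall enzymes (7 and 32). Under median-of-ratios scaling the balance turned in most of them (10 and 2 for the peroxisome, 3 and 0 for the ribosome, 12 and 2 for endocytosis, 8 and 3 for the TCA cycle). The same held for others (5 and 1 for glycolysis, 9 and 4 for oxidative stress, 11 and 9 for heat shock, 9 and 8 for G proteins, 15 and 9 for secondary metabolism), as it did in oxidative phosphorylation (4 and 1). Among these genes PEX11 (AOL_s00083g431), which divides peroxisomes, was higher (14.9 ± 4.79 against 239 ± 172 TPM, log2 fold change 3.73, adjusted p = 0.00186).

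**Figure D4:**
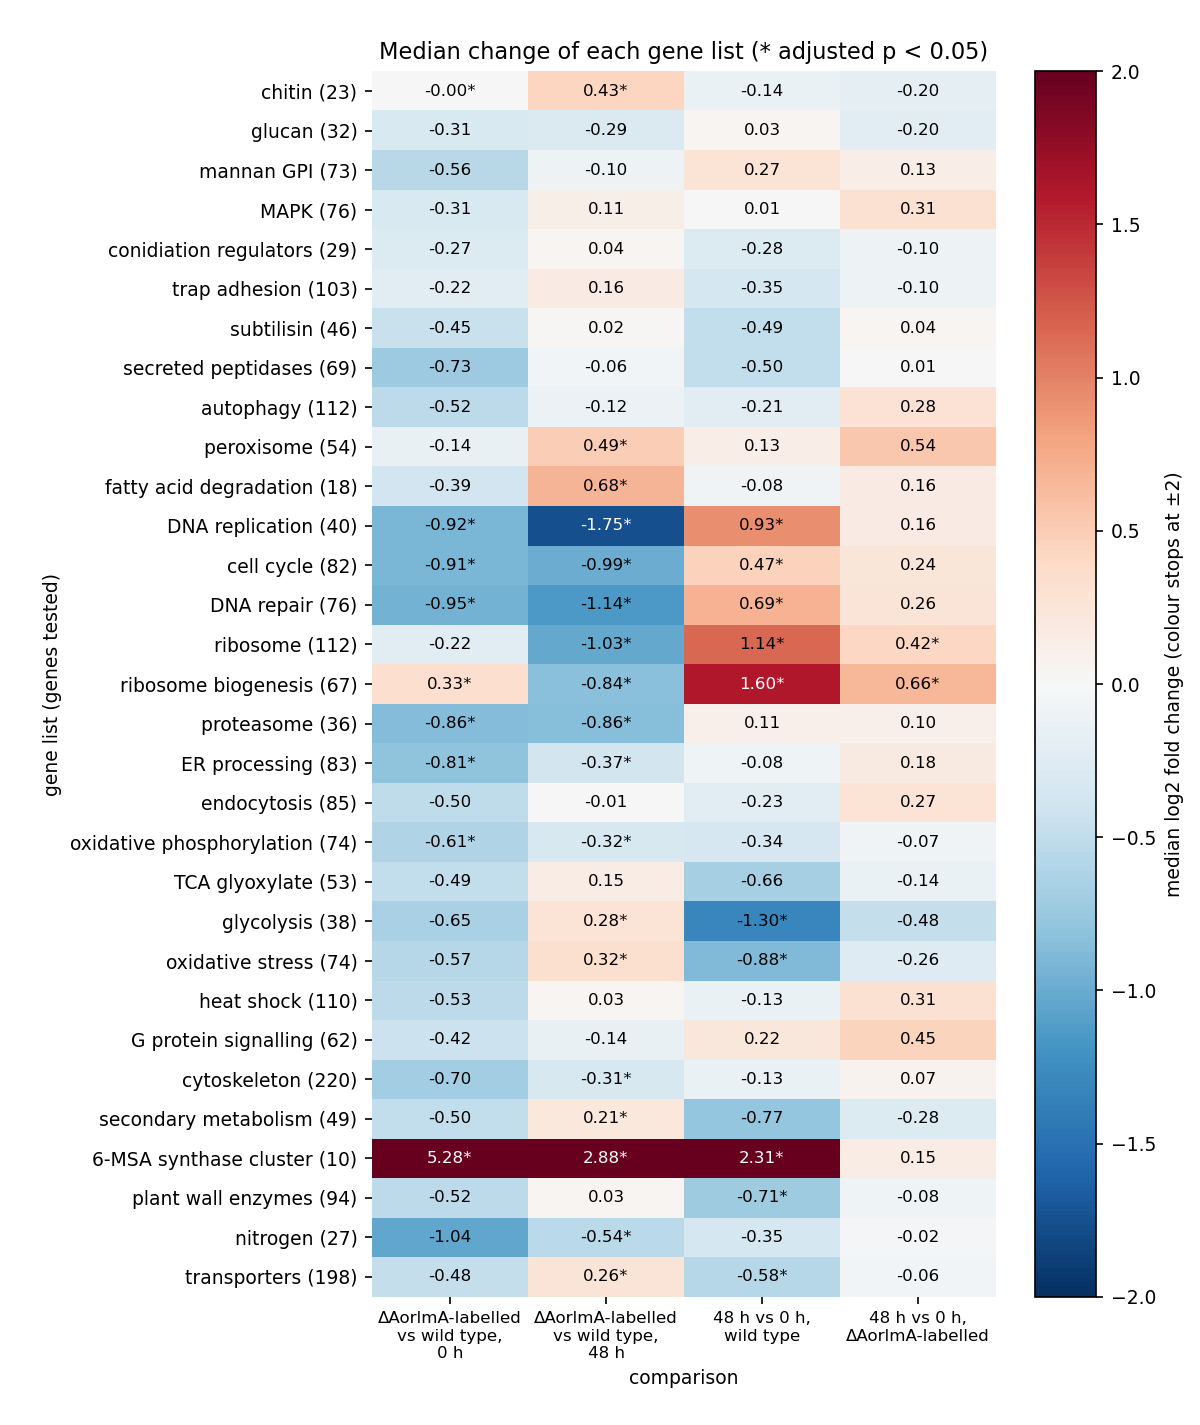
Median log2 fold change of the members of each of the 31 gene lists tested as sets (lines of the map, with the number of genes tested) in 4 comparisons (columns), with colour limited at 2 in either direction. An asterisk marks a camera adjusted p under 0.05 with the preset correlation; with an estimated correlation no list passes, and DNA replication ranges from -1.75 at 48 h between strains to 0.93 over time in the wild type.

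At 0 h limma called 3990 genes at an adjusted p under 0.05, 830 higher and 3160 lower in the libraries labelled ΔAorlmA, of which 728 and 2312 changed at least 2-fold. The median of all genes was shifted by -0.56, and median-of-ratios scaling, which moved it to -0.06, called 2378 genes (1335 higher and 1043 lower), while quantile normalization called 2817 (1249 and 1568). Without the first ΔAorlmA libraries the count was 4990 (900 higher and 4090 lower); without the third wild-type library it was 2096 and without the third ΔAorlmA library 2606.

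The comparison at 48 h asked which genes differ between the strains once traps have been induced. The cluster around the 6-methylsalicylic acid synthase gene was again higher in the libraries labelled ΔAorlmA, in 9 of 10 genes (10 adjusted over the list alone), with a median of 2.88 (camera adjusted p = 3.86e-07; adjusted p = 0.478 with an estimated correlation). The synthase AOL_s00215g283 had 3.95 ± 2.10 TPM in the wild type and 185 ± 163 TPM in the libraries labelled ΔAorlmA (n = 3 each, log2 fold change 4.64, SE 0.88, adjusted p = 0.00716), and the first library labelled ΔAorlmA was the lowest of them with 22.25 TPM. The oxidoreductase AOL_s00043g281 (20.5 ± 8.10 against 1770 ± 1331 TPM, log2 fold change 5.86), the trypsin-like AOL_s00078g418 (0.173 ± 0.0814 against 36.5 ± 23.2 TPM, 4.73) and AOL_s00081g143, with a glycolipid synthase domain (0.32 ± 0.288 against 30.2 ± 5.70 TPM, 4.57), were higher too. The oxidoreductase sirO gene AOL_s00007g346 was higher (log2 fold change 4.55, adjusted p = 0.0113), a call that ended without the third ΔAorlmA library (adjusted p = 0.0555). Lower were the P450 AOL_s00080g313 (98.7 ± 6.29 against 9.81 ± 7.05 TPM, -3.45) and the urea transporter DUR3 AOL_s00215g323 (74.3 ± 16.8 against 8.18 ± 5.80 TPM, -3.19). So were the ATP-grasp enzyme AOL_s00043g447 (48.4 ± 5.37 against 5.96 ± 0.419 TPM, -2.82) and the BRCT protein AOL_s00006g217 (67.4 ± 3.59 against 11.99 ± 10.6 TPM, -2.70). AOL_s00188g153, a membrane protein, had 5.61 ± 2.68 TPM in the wild type and is listed at 0 in the 3 libraries labelled ΔAorlmA.

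The lists of ribosomes, DNA replication and repair, the cell cycle, the proteasome and ER processing were lower at 48 h in the libraries labelled ΔAorlmA. Of 112 ribosomal protein genes 1 was higher and 78 lower (1 and 101 adjusted over the list alone, median -1.03, adjusted p = 2.31e-16), and of 67 ribosome biogenesis genes 0 and 26 (0 and 35, median -0.84, adjusted p = 3.62e-07). DNA replication had 29 of 40 lower and none higher (30 adjusted over the list alone, median -1.75, adjusted p = 2.27e-11), and DNA repair 41 of 76 lower and 0 higher (45 and 1 adjusted over the list alone, median -1.14, adjusted p = 2.27e-11). The cell cycle had 30 of 82 lower and 3 higher (45 and 3, median -0.99, adjusted p = 9.34e-07). The proteasome had 26 of 36 lower and 0 higher (27 and 0 adjusted over the list alone, median -0.86, adjusted p = 9.93e-09) and ER processing 28 of 83 lower and 2 higher (34 and 7, median -0.37, adjusted p = 0.0029). Each of these 7 had adjusted p = 0.478 with an estimated correlation. The nitrogen list had 6 of 27 lower and none higher (7 adjusted over the list alone, median -0.54, adjusted p = 0.0354, and adjusted p = 0.478 with an estimated correlation); its call ended without the first ΔAorlmA libraries (adjusted p = 0.0661). Oxidative phosphorylation (2 of 74 higher and 8 lower, 2 and 7 adjusted over the list alone, median -0.32, adjusted p = 0.04) and the cytoskeleton (11 of 220 and 45, 11 and 46, median -0.31, adjusted p = 0.0354) each had adjusted p = 0.652 with an estimated correlation. The former ended under median-of-ratios scaling (adjusted p = 0.197) and without the first ΔAorlmA libraries (0.144). The first ΔAorlmA library stood closest to the wild type. Without the first ΔAorlmA libraries 107 ribosomal protein, 48 ribosome biogenesis and 53 cell cycle genes were lower, while DNA replication had 31. Such larger counts are favoured by leaving out the library nearest the wild type.

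A further 6 lists, of peroxisomes, fatty acid breakdown, glycolysis, transporters, oxidative stress and chitin, were higher at 48 h. Of 54 peroxisome genes 14 were higher and 3 lower in the libraries labelled ΔAorlmA (14 and 3 adjusted over the list alone, median 0.49, adjusted p = 0.000942). Of 18 genes of fatty acid breakdown it was 5 and 1 (5 and 1, median 0.68, adjusted p = 0.00959), and of 38 of glycolysis 9 and 1 (9 and 1, median 0.28, adjusted p = 0.00435). Transporters had 27 of 198 higher and 11 lower (23 and 8 adjusted over the list alone, median 0.26, adjusted p = 0.000942) and oxidative stress 17 of 74 and 9 (17 and 10, median 0.32, adjusted p = 0.0387). The chitin list had 4 of 23 higher and 1 lower (4 and 1 adjusted over the list alone, median 0.43, adjusted p = 0.0291). These 6 had adjusted p = 0.478 with an estimated correlation. Glycolysis, oxidative stress and chitin did not pass with fry in place of camera (fry adjusted p = 0.134, 0.173 and 0.0697). Without the first ΔAorlmA libraries peroxisomes had 19 higher and 6 lower, fatty acid breakdown 6 and 2, and glycolysis 11 and 4. Transporters then had 44 and 18, oxidative stress 22 and 15, and chitin 8 and 4. Chitin synthase D (AOL_s00210g143) had 5.20 ± 0.68 against 22.2 ± 9.40 TPM (log2 fold change 1.83, SE 0.39, adjusted p = 0.00991), a call that ended without the third ΔAorlmA library (adjusted p = 0.0525), and the lower member, AOL_s00215g802, is a mitochondrial ribosomal protein (-1.07, adjusted p = 0.0173), whose call ended without the same library (0.0756). Secondary metabolism had 14 of 49 higher and 6 lower (14 and 6 adjusted over the list alone, median 0.21, adjusted p = 0.04, and adjusted p = 0.56 with an estimated correlation), a call that ended under median-of-ratios scaling (0.0647).

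The trap adhesion list had 15 of 103 members higher and 12 lower at 48 h (15 and 13 adjusted over the list alone) and did not pass as a set (adjusted p = 0.0557). AOL_s00193g63, a secreted protein of unknown function in that list, had 0.343 ± 0.14 against 5.09 ± 1.97 TPM (log2 fold change 2.13, adjusted p = 0.00178), while AOL_s00043g531, a lectin that ferries glycoproteins inside the cell, was lower (-1.82, adjusted p = 0.00595). Subtilisins had 7 of 46 higher and 3 lower (7 and 3 adjusted over the list alone); the called members include the inhibitor AOL_s00006g563 (4.03, adjusted p = 0.00716) and CPSF2 (AOL_s00110g295), which trims mRNA ends (-1.74, adjusted p = 0.0113), neither of them a subtilisin. The call of CPSF2 (AOL_s00110g295) ended without the third ΔAorlmA library (adjusted p = 0.0534). Secreted peptidases had 6 of 69 higher and 6 lower (5 and 4 adjusted over the list alone), among them guanine deaminase AOL_s00043g146 (1.86) and the chromatin factor subunit AOL_s00169g20 (-1.36), which are no peptidases. Their calls ended without the third wild-type library (AOL_s00043g146, adjusted p = 0.0565) and without the second ΔAorlmA library (AOL_s00169g20, 0.0624). The conidiation list had 5 of 29 higher and 2 lower (5 and 2 adjusted over the list alone). The gene fluG (AOL_s00043g361), which starts sporulation in Aspergillus, was lower (27.1 ± 1.59 against 7.21 ± 1.24 TPM, -1.79, adjusted p = 0.0236), a call that ended under quantile normalization and without the second ΔAorlmA library (adjusted p = 0.081). In the wall lists, the glucanosyltransferase gel3 (AOL_s00054g226) was lower (98.8 ± 14.7 against 24.9 ± 9.32 TPM, -2.001, adjusted p = 0.00716), as was the mannosyl donor enzyme DPM1 (AOL_s00004g269, -1.64, adjusted p = 0.00504). The glucan list had 2 of 32 higher and 2 lower (0 and 1 adjusted over the list alone), mannan and GPI proteins 1 of 73 and 15 (1 and 15), and MAP kinases 8 of 76 and 4 (8 and 4), with CDC42 (AOL_s00043g439), a switch of polar growth, lower (-0.88, adjusted p = 0.0146), a call that ended without the third wild-type library (adjusted p = 0.0586).

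At 48 h limma called 2234 genes, 861 higher and 1373 lower in the libraries labelled ΔAorlmA (784 and 1072 at least 2-fold). The median of all genes was -0.11, and 0.01 under median-of-ratios scaling, which called 2160 genes (1015 higher and 1145 lower). Without the first ΔAorlmA libraries the count was 4001 (1452 and 2549); leaving out single libraries gave 491 to 3093, the lowest without the third ΔAorlmA library.

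The strain differences of both times, which share no library, overlapped. Both come from the same fit with a shared spread per gene, so the values for independent lists may be too low. Of the 830 genes higher at 0 h and the 861 higher at 48 h, 326 were in both lists, where independent lists would share 76.4, and of the 3160 and 1373 lower genes 834 were in both, against 464. Higher at 0 h and lower at 48 h, or the reverse, were 23 and 37 genes. Across genes, which are not independent replicates, the log2 fold changes of both times had a Pearson correlation of 0.55.

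The third comparison asked what changed in the wild type between 0 h and 48 h of induction. No group was kept for 48 h without extract, so induction and 48 h of further growth cannot be told apart. Genes of ribosome production rose. Of 112 ribosomal protein genes 94 rose and 1 fell (103 and 1 adjusted over the list alone, median log2 fold change 1.14, camera adjusted p = 7.22e-21), and of 67 ribosome biogenesis genes 45 and 2 (47 and 2, median 1.60, adjusted p = 2.9e-17). DNA replication had 18 of 40 risen and 4 fallen (20 and 4 adjusted over the list alone, median 0.93, adjusted p = 0.000505) and DNA repair 29 of 76 and 8 (29 and 8, median 0.69, adjusted p = 0.000505). The cell cycle had 19 of 82 and 6 (10 and 5, median 0.47, adjusted p = 0.0259). Each of these 5 had adjusted p = 0.892 with an estimated correlation. DNA replication, DNA repair and the cell cycle did not pass with fry in place of camera (fry adjusted p = 0.0803, 0.125 and 0.497). BRX1 (AOL_s00215g251), an assembly factor of the large ribosomal subunit, rose from 14.5 ± 1.33 to 325 ± 33.0 TPM (n = 3 each, log2 fold change 4.39, SE 0.34, adjusted p = 1.2e-05). The beta-1,3-glucan-binding protein AOL_s00083g252 rose from 7.34 ± 5.80 to 299.7 ± 133 TPM (5.28) and its neighbour AOL_s00083g253, a glycosyl transferase, from 0.39 ± 0.624 to 38.7 ± 18.5 TPM (4.82). So did the F-box protein AOL_s00169g118 from 5.51 ± 1.47 to 218 ± 46.6 TPM (5.08) and the RNA-binding protein AOL_s00215g453 from 9.83 ± 2.14 to 196 ± 25.8 TPM (4.195).

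The lists of glycolysis, oxidative stress, plant wall enzymes and transporters were lower at 48 h in the wild type. Glycolysis had 4 of 38 genes risen and 24 fallen (5 and 25 adjusted over the list alone, median -1.30, adjusted p = 0.0047). Oxidative stress had 8 of 74 and 35 (9 and 38, median -0.88, adjusted p = 0.0109). Plant wall enzymes had 2 of 94 and 40 (2 and 39, median -0.71, adjusted p = 0.0123), and transporters 19 of 198 and 71 (19 and 71, median -0.58, adjusted p = 0.0405). Each had adjusted p = 0.892 with an estimated correlation, and the calls of plant wall enzymes and transporters ended under quantile normalization (adjusted p = 0.205 and 0.0987). Mitochondrial superoxide dismutase AOL_s00007g292, which also stood in the peroxisome list, fell from 172 ± 61.5 to 12.2 ± 2.40 TPM (log2 fold change -3.66, SE 0.46, adjusted p = 8.36e-05) and the cellulose-binding protein AOL_s00004g323 from 196 ± 22.3 to 2.42 ± 2.39 TPM (-6.17). Formamidase AOL_s00043g399 fell from 559 ± 101 to 9.86 ± 3.22 TPM (-5.72), the oxidase AOL_s00188g307 from 644 ± 255 to 10.7 ± 2.87 TPM (-5.73) and the protease inhibitor AOL_s00054g904 from 483 ± 307 to 3.70 ± 2.58 TPM (-6.57). The 6-methylsalicylic acid synthase cluster rose in 6 of 10 genes (7 adjusted over the list alone, median 2.31, adjusted p = 0.0047; adjusted p = 0.892 with an estimated correlation).

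Of the trap adhesion list 14 of 103 rose and 40 fell in the wild type (15 and 40 adjusted over the list alone), without passing as a set (adjusted p = 0.316). AOL_s00080g333 in that list fell from 194 ± 37.7 TPM (log2 fold change -6.37, adjusted p = 2.95e-05), and AOL_s00173g258 rose from 6.52 ± 0.847 to 66.0 ± 1.03 TPM (3.16, adjusted p = 6.31e-05). Subtilisins had 10 of 46 risen and 16 fallen (11 and 17 adjusted over the list alone), with subtilisin AOL_s00007g170 lower (6.93 ± 0.93 against 0.243 ± 0.0945 TPM, -2.67) and the peroxisomal Lon protease AOL_s00004g624, which is no subtilisin, higher (1.34). Secreted peptidases had 6 of 69 risen and 25 fallen (6 and 25 adjusted over the list alone; 13 and 20 under median-of-ratios scaling). The extracellular carboxypeptidase AOL_s00054g220 was among the fallen (-2.38), and the RNA helicase AOL_s00083g70 among the risen (2.97). In the wall lists 7 of 32 glucan genes rose and 7 fell (7 and 7 adjusted over the list alone), 2 of 23 chitin genes and 7 (2 and 7), and 18 of 73 mannan and GPI genes and 15 (18 and 15). Under median-of-ratios scaling these were 10 and 7, 4 and 5, and 22 and 13. The glucanase AOL_s00170g61 rose (19.0 ± 4.92 to 107 ± 7.69 TPM, 2.46, adjusted p = 0.000101), as did the wall protein ecm33 AOL_s00075g5 (2.75, adjusted p = 0.000185), while the glucanosyltransferase gas2 AOL_s00043g350 (-1.94) and the CFEM protein AOL_s00215g752 (-2.74) fell. Chitin synthase 8 (AOL_s00210g37) rose (0.98, adjusted p = 0.0182), a call that ended without the second wild-type library of 48 h (adjusted p = 0.0705), and the ankyrin AOL_s00004g380, no chitin enzyme, fell (-2.07). The regulator laeA (AOL_s00076g266), known to control secondary metabolism and sporulation, fell from 3.45 ± 0.129 to 0.813 ± 0.16 TPM (-1.30, adjusted p = 0.000635), a call that ended under quantile normalization. The conidiation list, where 5 of 29 rose and 10 fell (5 and 10 adjusted over the list alone), also held UTP20 (AOL_s00080g277), a ribosome assembly factor that rose (2.70). Of the peroxisome list 12 of 54 rose and 16 fell (12 and 16 adjusted over the list alone), which became 17 and 15 under median-of-ratios scaling; PEX14 (AOL_s00004g292), a docking protein of peroxisomal import, rose from 104 ± 2.07 to 445 ± 61.4 TPM (2.08, adjusted p = 0.000326). Acetyl-CoA acetyltransferase AOL_s00176g25 rose from 131 ± 53.6 to 770.2 ± 142 TPM (2.62). The MADS gene AOL_s00112g128 rose (0.87, adjusted p = 0.00507) and AOL_s00088g15 fell (-1.58, adjusted p = 0.00181).

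In the wild type limma called 4338 genes, 1650 risen and 2688 fallen (1340 and 2257 at least 2-fold), with a median of all genes of -0.25. Median-of-ratios scaling, with a median of -0.05, called 4460 (2253 and 2207) and quantile normalization 4262 (2273 and 1989). Without the first ΔAorlmA libraries, which enter here only through the shared spread, the count was 5361.

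The fourth comparison asked what changed in the strain labelled ΔAorlmA between 0 h and 48 h of induction. Here too, induction and further growth cannot be told apart. Ribosome biogenesis rose here as well, in 21 of 67 genes with none fallen (26 and 1 adjusted over the list alone, median log2 fold change 0.66, camera adjusted p = 0.00104). Of 112 ribosomal protein genes 5 rose (1 adjusted over the list alone, median 0.42, adjusted p = 0.00599). Both had adjusted p = 0.943 with an estimated correlation and adjusted p = 0.0731 without the first ΔAorlmA libraries. The F-box gene AOL_s00169g118 rose from 2.11 ± 1.996 to 113 ± 81.2 TPM (n = 3 each, log2 fold change 5.17, SE 0.51, adjusted p = 0.00033). Carriers of nitrogen compounds were among the 5 largest rises of annotated genes, the peptide transporter ptr2 AOL_s00097g310 (2.97 ± 2.36 to 91.5 ± 78.5 TPM, 4.26, adjusted p = 0.00295) and the amino acid permease GAP1 AOL_s00170g65 (18.3 ± 13.0 to 490.1 ± 528 TPM, 4.25, adjusted p = 0.00368). The cellulose-binding protein AOL_s00004g323 fell from 187 ± 73.3 to 3.74 ± 6.47 TPM (-6.28, adjusted p = 0.00129), glycerophosphodiesterase AOL_s00110g143 from 529 ± 219 to 16.3 ± 7.96 TPM (-4.97) and the oxidative cellulase AOL_s00169g245 from 121 ± 14.4 to 13.4 ± 17.0 TPM (-3.86).

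The trap adhesion list had 15 of 103 members risen and 17 fallen in the strain labelled ΔAorlmA (16 and 20 adjusted over the list alone). AOL_s00193g63 was among the former (1.86, adjusted p = 0.00187) and the ricin-type lectin AOL_s00215g496 among the latter (439 ± 138 to 64.1 ± 55.2 TPM, -3.05, adjusted p = 0.00269). The lectin AOL_s00078g374 fell (-3.44, adjusted p = 0.0193), a call that ended without the second 0 h library (adjusted p = 0.0862). Peroxisome genes had 14 of 54 risen and 3 fallen (16 and 4 adjusted over the list alone; 10 and 6 under median-of-ratios scaling) and did not pass as a set (adjusted p = 0.177), with the carrier PMP47A AOL_s00215g205 higher (1.63, adjusted p = 0.00289). Secreted peptidases had 12 of 69 risen and 5 fallen (13 and 5 adjusted over the list alone), which turned to 6 and 8 under median-of-ratios scaling. The aspartyl protease AOL_s00078g67 rose (1.88, adjusted p = 0.003) and barrierpepsin AOL_s00007g233 fell (-2.43, adjusted p = 0.00277). Plant wall enzymes had 8 of 94 risen and 13 fallen (8 and 14 adjusted over the list alone), transporters 23 of 198 and 25 (24 and 27), glycolysis 3 of 38 and 6 (3 and 6), and G protein signalling 10 of 62 and 3 (14 and 3). None of these lists passed as a set (adjusted p = 0.327, 0.415, 0.0717 and 0.0717), nor did trap adhesion (0.386) or secreted peptidases (0.775). The 10 genes of the 6-methylsalicylic acid synthase cluster had 0 risen and 0 fallen (limma, median 0.15). In the wall lists the glucanase AOL_s00170g61 rose (13.3 ± 3.15 to 87.8 ± 34.0 TPM, 2.59, adjusted p = 0.000697), as did ecm33 AOL_s00075g5 (2.01, adjusted p = 0.00606). The GPI protein AOL_s00054g382 fell (-1.60, adjusted p = 0.0127), a call that ended without the second 0 h library (0.0556). The chitin synthase export chaperone AOL_s00004g499 rose (1.24, adjusted p = 0.0448), a call that ended under median-of-ratios scaling (0.0675). The spore gene con-13 AOL_s00081g178, of the list of spore and hydrophobin genes with 4 tested members, rose (0.92 ± 0.183 to 3.22 ± 1.97 TPM, 1.05, adjusted p = 0.0325), a call that ended without the second 48 h library (0.109).

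In the strain labelled ΔAorlmA limma called 2009 genes, 1212 risen and 797 fallen (997 and 695 at least 2-fold), with a median of all genes of 0.14. Median-of-ratios scaling, with a median of -0.01, called 2084 (952 and 1132) and quantile normalization 1893 (981 and 912). A fit of the 2 groups alone called 438 (193 risen and 245 fallen), of which 428 were among the 2009. It estimates the spread from fewer libraries. The main fit shares the spread with the wild-type libraries, most of which resembled each other more closely. Its p-values for this comparison may therefore be too low. The count was 3420 (2073 and 1347) without the first ΔAorlmA libraries. Leaving out single libraries gave 720 to 3442.

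Both time courses, which share no library but share the spread per gene of the fit, overlapped. In both, 666 genes rose (1650 and 1212, against 214 for independent lists) and 637 fell (2688 and 797, against 229). Because of the shared spread the values for independent lists may be too low. The correlation of log2 fold changes across genes was 0.68. Genes that rose in the wild type and fell in the strain labelled ΔAorlmA, or the reverse, were 1 and 17.

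The last comparison asked which genes changed differently over time in the strains. Its values are the change in the libraries labelled ΔAorlmA minus that in the wild type. Ribosome genes rose less in the libraries labelled ΔAorlmA: the median difference was -1.03 for ribosome biogenesis (0 of 67 genes positive and 13 negative, 2 and 32 adjusted over the list alone, camera adjusted p = 2.99e-21). It was -0.81 for ribosomal proteins (0 of 112 and 1, 0 and 1 adjusted over the list alone, adjusted p = 3.46e-22). BRX1 (AOL_s00215g251) differed by -2.65 (adjusted p = 0.0195), a call that ended without the third wild-type library of 48 h (0.0594). DNA replication had a median of -0.69 (adjusted p = 9.16e-07) and DNA repair of -0.16 (adjusted p = 0.000135), with 0 single genes called in either list, whether over all genes or adjusted over the list alone. The 6-methylsalicylic acid synthase cluster had a median of -1.81 (0 genes over all genes, 0 and 3 adjusted over the list alone, adjusted p = 5.74e-05). The glucan list had -0.06 (0 and 2 of 32, 0 and 3, adjusted p = 0.0269) and glycolysis 0.93 (2 of 38 and 0, 8 and 0, adjusted p = 0.027). All 7 had adjusted p = 0.888 with an estimated correlation, and the calls of the glucan list and glycolysis ended without the first ΔAorlmA libraries (adjusted p = 0.107 and 0.186). With fry in place of camera only ribosome biogenesis passed of the 7 (fry adjusted p = 0.0494). FKS1 (AOL_s00054g491) differed by -2.08 (adjusted p = 0.0195), a call that ended without the second wild-type library of 0 h (0.0512). It had 71.5 and 233 TPM in the wild type and 397 and 294 TPM in the libraries labelled ΔAorlmA. The glucose transporter AOL_s00054g267 differed by 4.10 (SE 0.46, adjusted p = 0.00306) and the oxidase AOL_s00188g307 by 5.82 (SE 0.84, adjusted p = 0.011). The RGS protein AOL_s00043g257, which switches off G proteins, differed by 4.35 (adjusted p = 0.011), the SNF-related kinase AOL_s00054g163 by 3.63 and the alpha-glucosidase AOL_s00169g233 by 2.68. AOL_s00054g267 had 41.6 TPM at 0 h and 1.09 TPM at 48 h in the wild type, and 1.49 and 1.00 TPM in the libraries labelled ΔAorlmA; AOL_s00188g307 had 644 and 10.7 TPM, and 20.05 and 15.4 TPM. Trap adhesion genes had 9 of 103 positive and 0 negative (12 and 1 adjusted over the list alone; 3 and 2 under median-of-ratios scaling).

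The interaction was called for 414 genes, 302 positive and 112 negative, around a median of all genes of 0.34. Median-of-ratios scaling (median -0.02) called 335 (128 and 207) and quantile normalization 330 (115 and 215), which turns the balance, and 1349 were called without the first ΔAorlmA libraries (955 and 394). Leaving out single libraries gave 17 to 876, the lowest without the third wild-type library of 48 h.

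The authors' deposited table gives a call per gene for the 4 pairwise comparisons. It lists 2710 genes between strains at 0 h (1757 up and 953 down) and 2765 at 48 h (1809 and 956), and over time 4530 in the wild type (2053 and 2477) and 2518 in the strain labelled ΔAorlmA (1021 and 1497). Of those tested here (2572, 2633, 4306 and 2421), 100% had the same sign, and 1688, 1659, 3702 and 1591 were also called here. Both sets of calls come from the same libraries, so equal signs say little. The balance between strains was opposite, with 830 higher and 3160 lower here at 0 h, and 861 and 1373 at 48 h. It was also opposite over time in the strain labelled ΔAorlmA (1212 risen and 797 fallen here). Under median-of-ratios scaling 2003 of the authors' calls at 0 h were called here, and 1724, 3769 and 1740 of the others. That scaling called 1335 higher and 1043 lower at 0 h, and 1015 and 1145 at 48 h. Over time in the strain labelled ΔAorlmA it called 952 risen and 1132 fallen.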

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

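Results were taken up here by a fixed rule: a change over time that differed between the strains by the interaction test of limma. The rule for outlying samples covers groups of 4 to 10 and could not be used with 3 libraries per group. Single genes among those named, and lists tested as sets, are given with the difference (log2, change in the libraries labelled ΔAorlmA minus change in the wild type). The cause was not tested for any of them, and the groups of libraries themselves are examined under the other observations. What the exchange of libraries would show was written down before its result was seen.

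In all, 414 genes met the rule. Of the genes that stood out at 0 h, the oxidase AOL_s00188g307 differed by 5.82, the glucose transporter AOL_s00054g267 by 4.10, the mitochondrial carrier AOL_s00215g29 by 3.88, the ricin-type lectin AOL_s00193g183 by 4.48, the subtilase AOL_s00054g992 by 3.17, the mannosidase AOL_s00076g222 by 1.57 and the CFEM protein AOL_s00215g752 by 1.53. FKS1 (AOL_s00054g491) differed by -2.08 and BCS1 (AOL_s00007g336) by -1.60. Of those that stood out at 48 h, the trypsin-like AOL_s00078g418 differed by 3.05, AOL_s00081g143 by 3.80 and AOL_s00193g63 by 2.25. Of those that changed over time, the glycosyl transferase AOL_s00083g253 differed by -3.69, BRX1 (AOL_s00215g251) by -2.65, the protease inhibitor AOL_s00054g904 by 6.13, formamidase AOL_s00043g399 by 3.79, subtilisin AOL_s00007g170 by 1.99, carboxypeptidase AOL_s00054g220 by 1.66, superoxide dismutase AOL_s00007g292 by 2.68 and the acetyltransferase AOL_s00078g525 by 3.09. The lowest adjusted p-values belonged also to AOL_s00076g259 (3.275), listed at 0 in every library but those labelled ΔAorlmA of 48 h, and to AOL_s00078g570 (4.27), AOL_s00079g114 (2.87), the RGS protein AOL_s00043g257 (4.35), the alpha-glucosidase AOL_s00169g233 (2.68), AOL_s00079g308 (4.56), the SNF-related kinase AOL_s00054g163 (3.63) and AOL_s00110g83 (1.75).

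The calls of 17 of these 28 genes ended without the third wild-type library of 48 h, and without other libraries fewer ended, from 0 to 16. The 11 genes called whichever library was left out were AOL_s00188g307, AOL_s00054g267, AOL_s00193g183, AOL_s00076g259, AOL_s00078g570, AOL_s00079g114, AOL_s00043g257, AOL_s00169g233, AOL_s00079g308, AOL_s00054g163 and AOL_s00110g83. Some were already low at 0 h in the libraries labelled ΔAorlmA, with little room to fall. At 0 h AOL_s00110g83 had 1.41 to 1.84 TPM in the wild type and 0 there. AOL_s00079g114 had 14.36 to 22.12 and 0.78 to 2.02 TPM, and AOL_s00169g233 5.5 to 7.89 and 0.13 to 0.68 TPM. Their difference over time cannot be told apart from the strain difference at 0 h. AOL_s00079g308 instead rose in the libraries labelled ΔAorlmA, from 13.19 to 16.07 TPM at 0 h to 122.58 to 517.44 TPM. BCS1 (AOL_s00007g336, adjusted p = 0.0487) and AOL_s00215g752 (0.0489) passed barely, and each lost its call in 10 of the 12 fits with a library left out.

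Among lists, the median difference was -0.061 for glucan, -0.69 for DNA replication, -0.16 for DNA repair, -0.81 for the ribosome, -1.03 for ribosome biogenesis, 0.93 for glycolysis and -1.81 for the 6-methylsalicylic acid synthase cluster. The median of all genes was itself shifted by 0.34, so a list near that value differs little from the rest.

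Whether chance in the grouping of libraries could give 414 calls was tested by exchanging libraries. Of 100 ways to exchange strain labels within both times, 7 gave at least as many calls, the real grouping included, and the highest other count was 4551, several times the real count, which points to structure of the samples. That regrouping exchanges the strain labels at 48 h, so that the strain difference of both times enters as the interaction. Besides it and the real grouping, 5 regroupings reached 414, of which 4 exchange all or 2 of the 3 libraries of each strain at a time, and so carry much of the strain difference; the remaining regrouping (470 calls) exchanges a single pair, the first library labelled ΔAorlmA at 48 h and a wild-type library. Such regroupings are a poor measure of chance for an interaction, and whether chance can be excluded was left open.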

How the results depend on the processing

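Fits were repeated under other settings, fixed before the data were examined, and under 3 added after the result was seen (precision weights, the first libraries labelled ΔAorlmA left out, quantile normalization for lists). Among named genes 2146 results stayed the same, 61 became weaker, 3 stronger and 13 reversed; the RLM1-type gene AOL_s00078g125 stayed the same between strains in all 34. Among lists 107 stayed and 77 became weaker, and among counts 88 stayed and 37 moved by more than 1.5 times.

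At 0 h (3990 genes) median-of-ratios scaling called 2378. Leaving out single libraries gave 2096 (without the third wild-type library) to 4428 (without the first ΔAorlmA library), and 2606 without the third ΔAorlmA library. At 48 h (2234) the count was 4001 without the first ΔAorlmA libraries. Single libraries gave 491 (without the third ΔAorlmA library) to 3093 (without the first), 762 without the second, and 1225, 861 and 697 without wild-type libraries 1, 2 and 3. Over time in the wild type (4338) they gave 3235 to 3831. Over time in the strain labelled ΔAorlmA (2009) a fit of its groups alone called 438 and the fit without the first ΔAorlmA libraries 3420. Single libraries gave 720 (without the second of 0 h) to 3442 (without the first of 0 h), with 1215 without the third of 0 h and 1055 without the second of 48 h.

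The interaction (414) had 260 calls with a pseudocount of 0.1, 245 with a mean of at least 5 TPM and 1349 without the first ΔAorlmA libraries. Single libraries gave 17 (without the third wild-type library of 48 h) to 876 (without the first ΔAorlmA library of 48 h). Without wild-type libraries 1, 2 and 3 of 0 h it was 238, 34 and 130, and without 1 and 2 of 48 h it was 240.0 and 47. Without ΔAorlmA libraries 2 and 3 of 0 h it was 675 and 106, and without those of 48 h 209 and 98. The replicate number as a block gave 3789, 2055, 4241, 1766 and 348 calls, and replicate numbers do not pair: 5 of 18 pairs with the same number had a correlation of residuals above 0.1 (median 0.025).

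With an estimated correlation 0 lists passed in each of the 5 comparisons. Fry in place of camera called 19 lists at 0 h and 0 over time in the strain labelled ΔAorlmA, and median-of-ratios scaling 11 for the interaction. Fry asks whether a list changed at all, so the shift of all genes at 0 h counts toward it. Its calls there were downward but for the 6-methylsalicylic acid synthase cluster, and ribosome biogenesis (fry adjusted p = 0.43) and chitin (0.174) were not called. Calls that ended with fry also include the cytoskeleton (0.0611) and secondary metabolism (0.245) at 48 h, and the cluster over time in the wild type (0.0803).

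Reversed signs touched only MADS genes that were not called. AOL_s00112g128 at 0 h (-0.00) had 0.55 with median-of-ratios scaling, 0.039 with quantile normalization and -0.0348 to 0.046 with single libraries left out. AOL_s00088g15 at 48 h (-0.04) had 0.093, 0.044 and -0.18 to 0.13. AOL_s00078g125 over time had 0.16, 0.020 and -0.25 to 0.084 in the wild type (-0.06), and -0.50 to 0.087 in the strain labelled ΔAorlmA (-0.19) with single libraries left out.

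Calls lost under a scaling were AOL_s00088g15 at 0 h, laeA (AOL_s00076g266) over time in the wild type, fluG (AOL_s00043g361) at 48 h, the endochitinase AOL_s00215g801 at 0 h and AOL_s00004g499 over time in the strain labelled ΔAorlmA. Precision weights lost AOL_s00079g114 and AOL_s00079g308 for the interaction.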

Other observations

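Single genes of nitrate and ammonium use, picked by hand after the results were seen, were lower in the libraries labelled ΔAorlmA. The nitrate transporter AOL_s00004g610 had a log2 fold change of -3.71 at 0 h and -2.59 at 48 h, the ammonium transporter MEP2 (AOL_s00043g163) of -2.87 and -2.61, and nitrite reductase AOL_s00210g162 of -1.70 and -1.68. The methyltransferase AOL_s00079g163, which makes the siroheme that nitrite reductase carries, had -2.63 and -2.47. Nitrate reductase AOL_s00210g163, next to nitrite reductase in the genome, had -1.29 at 0 h and did not pass at 48 h (-0.81). All the others passed with limma adjusted p-values of at most 0.0205. In fungi these genes answer to the nitrogen source, but as groups they gave no firm result. The nitrogen list did not pass at 0 h (adjusted p = 0.134) and passed at 48 h only with the preset correlation. The KEGG pathway of nitrogen metabolism did not pass at either time (adjusted p = 0.758 and 0.942), with 2 of 15 genes higher and 8 lower at 0 h (median -1.11) and 1 higher and 2 lower at 48 h.

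KEGG pathways, read only after the results were seen and so exploratory, add genes of RNA and protein handling. At 48 h 58 of 95 spliceosome genes were lower and 0 higher (median -0.91), 21 of 25 mismatch repair genes and 18 of 21 homologous recombination genes (median -1.78 in both), and 44 of 94 RNA transport genes. The aminoacyl-tRNA synthetases were lower at 0 h (31 of 42, median -0.98) and at 48 h (20 of 42, median -0.82), as was N-glycan biosynthesis (23 of 31 and 17 of 31). Thiamine metabolism was higher at 48 h (5 of 14, median 0.82). With an estimated correlation adjusted p was 0.998 at 0 h and 0.727 at 48 h for these pathways. Among genes without annotation, AOL_s00080g84 went from 0.857 TPM in the wild type to 1166 TPM in the libraries labelled ΔAorlmA at 0 h.

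Genes changed in the libraries labelled ΔAorlmA lay next to each other more often than random sets. The 326 genes higher at both times formed 50 neighbouring pairs, against a median of 10 and a maximum of 19 in 1000 random draws, and the 834 lower at both times formed 114, against 64 and 90. The longest run was AOL_s00215g275 to AOL_s00215g283. A further run, AOL_s00210g119 to AOL_s00210g122, holds an alcohol dehydrogenase, thiamine pyrophosphokinase and a peroxisomal thiolase, with median log2 fold changes of 2.21 at 0 h and 2.32 at 48 h. A run of 4 unannotated genes, AOL_s00097g420 to AOL_s00097g423, had 3.45 and 3.31. Among the lower genes, a run of 5, AOL_s00079g12 to AOL_s00079g16, had -1.21 and -1.40.

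Of the tests on the 3 patterns that follow, 4 were chosen after the result was seen: the exchange of strain labels, the partial transcript, the exchange with a wild-type library and the share of wild-type RNA needed. What the others, the neighbour test and the regrouping of libraries would show was written down before their results were seen. For the pairwise comparisons regroupings allow only 10 splits, 1 of which is the real one in each, so the splits are too few to exclude chance: the real counts were 3990, 2234, 4338 and 2009 and the highest others 3, 58, 0 and 37.

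The RLM1-type gene AOL_s00078g125 was higher in the libraries labelled ΔAorlmA, where a deletion of the whole gene would leave none. If the whole gene was deleted, an exchange of the strain labels predicts 0 TPM in the libraries labelled wild type, whose lowest value was 27.94 TPM. If a part of the gene is still transcribed and counted, exchanged labels could also give lower values there. The test therefore cannot decide on an exchange. A scaling effect is argued against by the smallest log2 fold change over 2 scalings and both times, 1.57. Transcription of a part of the gene outside the deletion could give the 1.60 seen at 0 h, and a value per whole gene cannot tell. Reads placed along the gene would test it; the other annotated MADS genes were not lost either, with lowest values in the libraries labelled ΔAorlmA of 175.51 TPM (AOL_s00112g128) and 7.37 TPM (AOL_s00088g15).

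The median gene was lower in the libraries labelled ΔAorlmA at 0 h, by -0.56. A larger share taken by a few abundant genes would vanish once the 50 most abundant of either group are left out, and the median was then -0.50. A length bias would leave some class of coding length near 0, and the highest of 10 classes had -0.52; values near the floor would spare genes of at least 50 TPM, which had -0.37. The shift was -0.54 up to 5 TPM, -0.73 from 5 to 20 TPM, and smaller at each higher level, down to -0.11 above 1000 TPM, where 133 genes held 33.0% of the TPM in the wild type and 38.0% in the libraries labelled ΔAorlmA. TPM adds up to the same total in every library, so an even change in total RNA per cell would cancel and cannot give the shift. The share of TPM moved toward abundant genes as a class. Genes of 50 to 200 TPM held 24.3% in the wild type and 21.3% in the libraries labelled ΔAorlmA, and genes of 200 to 1000 TPM 30.7% and 31.8%. What lies behind this change in composition was not tested.

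The first library labelled ΔAorlmA at 48 h lay close to the wild type. An exchange with a wild-type library is argued against, since every wild-type library of 48 h stayed nearer to its own group by at least 0.0327 in correlation. Wild-type RNA mixed into the library predicts that genes low at 0 h move to the wild type as far as the others, and the difference was -0.00662 (interval -0.11 to 0.113). A mixture at the share that the median position needs is argued against by 12 of 4829 genes under 0.3 of the lowest wild-type value, the lowest being AOL_s00043g447 with 15.2% (6.44 against 42.45 TPM). A smaller share, up to 15.2%, or a culture that differed, could remain, and strain markers in the reads would test both.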
